A study of Mus musculus with 63 samples.

How the data were processed

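Hearts of mice were profiled by RNA sequencing of polyadenylated RNA in 63 libraries, read from single ends without strand information. The libraries fall into 14 groups by age (P1, P21, 5 weeks), genotype (Mfn2AA, Mfn2wt, tet-off, nontransgenic) and library batch. Per the labels, the libraries of each age were prepared together. Nontransgenic hearts of P21 and 5 weeks were made again in the P1 batch from the same total RNA, except 5wk_ntg_15933-3, made in that batch only. Age and batch are therefore the same split for genotype groups, and ages were compared only among the nontransgenic libraries of the P1 batch.

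The authors aligned reads to the mouse genome, build mm10, with Bowtie2 and TopHat2 2.0.10, and counted reads per gene with HTSeq. The deposited count table holds the raw read count of each of 23429 genes in each library, with no normalization. The authors also made a table of FPKM with Cufflinks 2.1, which is the deposited table that lists the human transgene. The deposited annotation holds coordinates of exons (other unit: base positions). Every library had a column in both tables, and 20337 genes had a read in at least 1 library.

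Total counts per library ran from 4557894 to 14844064 in the P1 batch, 5292335 to 24339146 in the P21 batch and 7396727 to 23732780 in the 5-week batch. Counting is only part of the error, as libraries of a group differ by more than counting gives. The share of changed genes recovered was tested on simulated data with the group sizes and depths of the genotype comparisons and 200 changed genes. With edgeR 7.46% to 69.7% of them were called at 1.5-fold, at 2-fold 43.3% to 92.5%, at 4-fold 84.8% to 100%, and 1.98% to 8.65% of the calls were false. With DESeq2 5.46% to 19.4% of the calls were false on the same data. The simulated genes varied independently of each other, with no shift shared by many genes of a library. These shares therefore do not cover false calls or losses from such shifts in the real libraries.

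Genes were tested with edgeR 4.0.16 (TMM scaling, its filter by expression, quasi-likelihood F test) in R 4.3.3, with a fit per age of its 4 genotype groups. Genes with an adjusted p (Benjamini-Hochberg) under 0.05 within a comparison were called. The 18 comparisons were 4 between genotypes at each of 3 ages, 2 between ages, 2 of the change of the Mfn2AA to Mfn2wt difference with age, and 2 between batches of the same RNA, the last with the heart as a block. The difference of the age effects is confounded with batch only where batch acts differently on the genotypes. Fold changes are log2 with their standard error.

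A total of 38 gene lists (25 of pathways, 10 of cell types, 3 technical) was written down by hand. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 at its preset correlation of 0.01, and again with the correlation estimated from the data. Members were also counted with the adjustment over the list alone. Maturation sets were the genes called and changed at least 2-fold from P1 to P21. Their adjustment over 6 sets was added after the data were seen, and the count of settings that moved a set used the unadjusted p. The human transgene was compared by exact permutation of log2 FPKM.

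Genes named in the report followed a rule. In every comparison it took the transgene, Mfn2, Park2 and Pink1. From each list it took up to 4 called members with the greatest change, and up to 2 uncalled ones. It also took the 10 greatest rises and 10 greatest falls among called genes whose groups do not overlap and whose higher mean is at least 1 CPM (counts scaled to library size). Unnamed genes, the transgene and 6 genes tied to sex were left out of that last part, since sex is not given. Some genes that the rule selects are not reported here. Sel1l2, named in the closing section, was chosen after its values were seen. The comparisons, lists, this rule and most of the other settings below were set before the data were examined.

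Other settings chosen in advance were RLE scaling, no filter, DESeq2 1.42.0, limma on log2 of FPKM with a pseudocount of 1 (mean of at least 1 in a group), fits of 2 groups alone, the other control line, the title number as a block, the subtraction of the difference between the control lines, batch as a term, each age in its own batch, and leaving out each library in turn. For the list tests, maturation sets and shared genes they were the estimated correlation, other sets or a fold of 4, and a mean of at least 10 CPM. Those chosen after the data were seen were a fit without the 5 libraries of lowest depth at 5 weeks, atrial and adipocyte marker scores as terms at P21, and a correction for GC content by lowess with a span of 0.3. Figures were drawn with matplotlib 3.10.9. Raw reads were not used here.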

Results

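RNA sequencing measured gene expression in 63 libraries from mouse hearts of the FVB/N strain background at 3 ages, postnatal day 1 (P1), postnatal day 21 (P21) and 5 weeks. Transgenic hearts expressed human mitofusin 2, a protein of the outer mitochondrial membrane that fuses mitochondria and, once phosphorylated by the kinase PINK1, binds the ubiquitin ligase Parkin. One line expressed the normal human protein (Mfn2wt). The other expressed a form in which a threonine and a serine, the residues that PINK1 phosphorylates, were replaced by alanine (Mfn2AA). The controls were hearts with the tet-off driver transgene alone (tet-off) and nontransgenic hearts.

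The P1 groups held 3 Mfn2AA, 4 Mfn2wt, 5 tet-off and 6 nontransgenic libraries. The P21 groups held 6, 6, 5 and 6 libraries in the same order, and the 5-week groups held 4, 4, 3 and 4. The remaining 7 libraries were nontransgenic hearts of P21 (3) and 5 weeks (4) prepared together with the P1 libraries. Total counts ran from 4557894 to 24339146 per library, over 23429 annotated genes. Libraries are named below by their deposited titles. The nuclear ribosomal repeat Rn45s took 1.98% to 34.4% of the counts. Its share in 5-week Mfn2wt hearts was 16.7% ± 12.8 (SD, n = 4) against 5.81% ± 2.06 (SD, n = 4) in Mfn2AA hearts of that age.

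Transcripts of the human transgene, read from the FPKM table, had group means far above those of the controls in both transgenic lines at every age. Their mean was 2092 ± 303 FPKM (SD, n = 3) in Mfn2AA and 339 ± 105 (SD, n = 4) in Mfn2wt hearts at P1, and 5319 ± 2059 (SD, n = 6) against 1588 ± 143 (SD, n = 6) at P21. At 5 weeks the order turned, with 540 ± 242 (SD, n = 4) in Mfn2AA and 1469 ± 215 (SD, n = 4) in Mfn2wt hearts. Group means of the hearts labelled as without the transgene ran from 5.24 to 82.5 FPKM. Some single libraries lay nearer each other, with 336 FPKM in 5wk_Mfn2AA_10287-8 and 190 in 5wk_tetoff_10289-1. At P1 it was 264 FPKM in P1_Mfn2wt_10546-3 and 155 in P1_tetoff_10587-1. The transgenic lines were not tested against the controls for this signal. Exact two-sided permutation tests of log2 FPKM between the lines gave adjusted p = 0.0286 at P1, 0.00649 at P21 and 0.0286 at 5 weeks over the 3 ages. At P1 and 5 weeks the unadjusted p, 0.0286, was the smallest that these group sizes allow. Comparisons of Mfn2AA with Mfn2wt, and their change with age, therefore cannot separate the mutated residues from the transgene level.

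**Figure D1:**
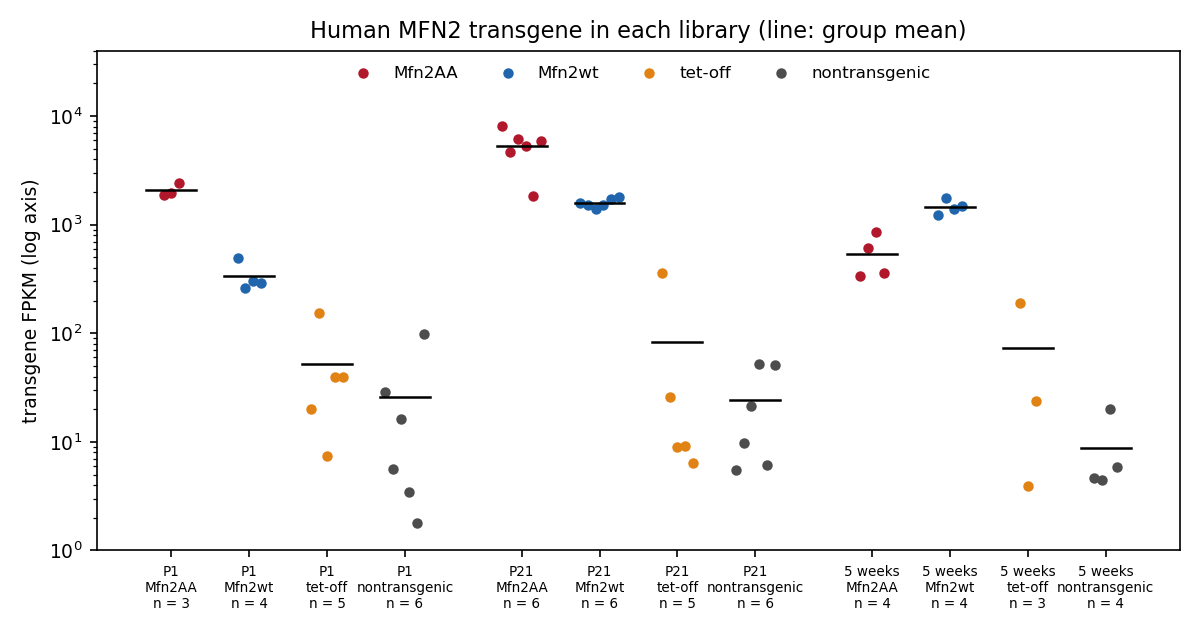
Human MFN2 transgene in each library, in FPKM on a log axis, for the 4 genotypes at each age; each point is a library and each line a group mean. The Mfn2AA libraries lay above every Mfn2wt library at P1 and P21 and below every one of them at 5 weeks, where the group means were 540 and 1469 FPKM.

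The endogenous mouse Mfn2 gene (chromosome 4, 147873595 to 147904819, build mm10) fell in 5-week Mfn2AA hearts, with a log2 fold change of -0.74 ± 0.11 (SE, n = 4 and 4) against Mfn2wt and -0.63 ± 0.11 (n = 4 and 3) against tet-off hearts. The second call was lost with limma on FPKM (-0.37, adjusted p = 0.0564). Mfn2 passed the test in no other genotype comparison. In nontransgenic hearts it rose by 0.72 ± 0.10 from P1 to P21 and by 0.37 ± 0.11 from P21 to 5 weeks. The second rise missed the threshold without the P1-batch libraries of P21_ntg_10547-1 or P21_ntg_10547-5 (adjusted p = 0.147 and 0.0546), and of 5wk_ntg_15927-6 or 5wk_ntg_15928-7 (adjusted p = 0.0589 and 0.0757). It also missed it without the filter on low counts (adjusted p = 0.0505). Pink1, which encodes the kinase, fell by 1.30 ± 0.21 (log2, SE) in 5-week Mfn2AA hearts against Mfn2wt and by 1.51 ± 0.22 against tet-off, and rose by 0.36 ± 0.12 against Mfn2wt at P21 (adjusted p = 0.0414). That P21 call was lost in 10 of 20 alternatives. It was lost without P21_Mfn2AA_10534-1, P21_Mfn2AA_10534-2, P21_Mfn2AA_10534-4 and P21_Mfn2AA_10534-6 (adjusted p = 0.0636, 0.0886, 0.0686 and 0.0936), without P21_Mfn2wt_10547-8, P21_Mfn2wt_10547-9 and P21_Mfn2wt_10583-5 (0.0702, 0.111 and 0.0713), and when the control-line difference was subtracted (0.590). Park2, which encodes Parkin, fell in 5-week Mfn2AA against Mfn2wt hearts, at -0.61 ± 0.19 (adjusted p = 0.018), and lost its call without 5wk_Mfn2wt_15934-5 (adjusted p = 0.0678), with limma on FPKM (0.440), when the control-line difference was subtracted (-0.41, adjusted p = 0.352) and without the libraries of lowest depth (-0.38, adjusted p = 0.428).

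At P1 the mutated residues and the transgene level both separate Mfn2AA from Mfn2wt hearts. These hearts differed in 17 of 13653 genes tested, 9 higher and 8 lower in Mfn2AA (n = 3 and 4). Higher were the olfactory receptor gene Olfr541, by 5.30 ± 0.58 (log2 fold change ± SE here and below), the nuclease-like gene Endod1, by 3.26 ± 0.24, the growth factor gene Fgf1, by 1.79 ± 0.35, and Stbd1, which binds glycogen, by 1.64 ± 0.32. Lower were Macrod2, which encodes an ADP-ribose hydrolase, at -3.28 ± 0.19, Ndufaf5, which lies near it on chromosome 2, at -0.77 ± 0.15, Ramp1, a receptor partner, at -0.63 ± 0.12, and the RNA-binding Hnrnpc, at -0.53 ± 0.09. Of these, Fgf1, Stbd1 and Ndufaf5 each lost the call in 9 of 14 alternatives, Ramp1 in 7 and Hnrnpc in 10. Against tet-off hearts (n = 3 and 5) 1 gene passed, Olfr541 again, at 5.35 ± 0.56, where edgeR gave 1140 genes at an unadjusted p under 0.05, DESeq2 16 genes without Olfr541 (adjusted p = 0.0856) and limma on FPKM 7.

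Of the fixed gene lists, 11 of 37 passed the set test in Mfn2AA against Mfn2wt at P1 with its preset correlation and 0 with an estimated one, and no list in this paragraph had a member that passed on its own. The 36 genes of complex I had a median of -0.13, the 25 genes of complexes II to IV -0.20 and the 17 of ATP synthase -0.20, each with adjusted p = 0.821 with an estimated correlation. The circadian clock genes had a median of 0.24, with 7 of 18 higher and 1 lower adjusted over the list alone (adjusted p = 0.0705 with an estimated correlation). Atrial cardiomyocyte markers had a median of -0.53 and macrophage markers -0.25 (adjusted p = 0.821 with an estimated correlation for both).

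The P1 count of 17 in Mfn2AA against Mfn2wt fell to 4 without P1_Mfn2AA_10586-3, to 3 without P1_Mfn2AA_10586-7, and to 3, 6, 7 and 7 without P1_Mfn2wt_10546-1, P1_Mfn2wt_10546-3, P1_Mfn2wt_10546-6 and P1_Mfn2wt_10546-9. When the control-line difference was subtracted 1 gene was called, among the 17, and Endod1 lost its call (adjusted p = 0.965). The single call against tet-off hearts became 22 without P1_Mfn2AA_10619-1. With DESeq2 the first count was 62 (limma on FPKM 6, of which 4 were higher and 2 lower), and with size factors of the RLE method 6 higher and 8 lower; DESeq2 called 12 higher and 4 lower against tet-off.

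Mfn2wt hearts at P1 differed from nontransgenic hearts in 20 of 13653 genes, 12 higher and 8 lower (n = 4 and 6). The labels used here do not say whether Mfn2wt hearts carry the tet-off driver, and against tet-off hearts they differed in 80 genes at P1, 821 at P21 and 130 at 5 weeks. Macrod2 rose by 2.87 ± 0.14. The cell cycle inhibitor Cdkn1a rose by 0.69 ± 0.12, the crosslinking enzyme Tgm2 by 0.55 ± 0.11, the glycolytic Pgam1 by 0.46 ± 0.09 and the sodium pump subunit Atp1b1 by 0.41 ± 0.08. The clock gene Per3 was lower, at -0.90 ± 0.13, the nitric oxide synthase Nos2 at -0.90 ± 0.18 and the splicing regulator Rbfox1 at -0.84 ± 0.15. Of 18 alternatives 2 ended the call of Per3, 7 that of Cdkn1a, 13 that of Tgm2, 10 that of Rbfox1, and 12 each those of Pgam1, Atp1b1 and Nos2.

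Natriuretic and cardiac stress genes had a median of 0.49 in that comparison at P1, with 1 of 20 called and 11 higher adjusted over the list alone (adjusted p = 0.166 with an estimated correlation). Fetal sarcomere isoforms had a median of 0.70 with 0 of 15 called and 9 higher and 1 lower adjusted over the list alone (adjusted p = 0.177 with an estimated correlation). Atrial markers moved with them, at a median of 0.82 with 0 of 13 called and 10 higher over the list alone (adjusted p = 0.427 with an estimated correlation). The 13 mitochondrially encoded genes had a median of -0.92, with 0 called and 11 lower adjusted over the list alone (adjusted p = 0.268 with an estimated correlation).

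Leaving out 1 library gave 1, 5, 85 and 11 genes without P1_Mfn2wt_10546-1, P1_Mfn2wt_10546-3, P1_Mfn2wt_10546-6 and P1_Mfn2wt_10546-9, 115 without P1_ntg_10546-4, and 3, 5, 2, 3 and 2 without P1_ntg_10582-1, P1_ntg_10582-2, P1_ntg_10582-3, P1_ntg_10582-4 and P1_ntg_10582-5, against the 20 of all libraries. All 4 Mfn2wt libraries share a title number with 1 of the 6 nontransgenic ones, and with that number as a block 1 gene was called, among the 20. DESeq2 called 183 genes and limma on FPKM 12, of which 9 were higher and 3 lower; correction for GC content gave 13 higher and 17 lower.

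The tet-off and nontransgenic lines at P1, compared to show what the driver line alone brings, differed in 177 of 13653 genes, 108 higher and 69 lower in tet-off (n = 5 and 6), and 25 by at least 2-fold. Endod1 rose by 3.14 ± 0.20. The actin gene Acta2 rose by 1.2 ± 0.24, the myosin light chain Myl9 by 1.11 ± 0.19, the mitochondrial Mgarp by 1.82 ± 0.36 and the keratin Krt80 by 1.21 ± 0.18. Mural and smooth muscle markers as a list did not pass (adjusted p = 0.204), with 1 of 14 higher (3 adjusted over the list alone). The flavin monooxygenase Fmo1 was lower, at -1.44 ± 0.23, Nipal4 at -1.73 ± 0.30 and the ciliary Ttc30b at -1.27 ± 0.19. Of 22 genes of mitochondrial fusion, fission and transport 1 rose (6 adjusted over the list alone, median 0.13, adjusted p = 0.545 with an estimated correlation), and of 21 ion channel and gap junction genes 2 fell (2 over the list alone, median -0.22, adjusted p = 0.545 with an estimated correlation).

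Without 1 library the P1 control-line count was 89, 73 and 90 (P1_ntg_10582-3, P1_ntg_10582-4 and P1_ntg_10582-5), 355 (P1_tetoff_10587-1), and 87, 101 and 80 (P1_tetoff_10587-3, P1_tetoff_10619-2 and P1_tetoff_10619-3) against 177. DESeq2 called 432 and limma on FPKM 93, and GC correction gave 106 higher and 110 lower.

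Mfn2AA and Mfn2wt hearts at P21 differ in transgene level as well as in the mutated residues. In this comparison 1862 of 13585 genes were called, 1021 higher and 841 lower in Mfn2AA (n = 6 and 6), and 291 by at least 2-fold. Genes of the integrated stress response, a program that ATF4 drives when translation or mitochondria are disturbed, fell in Mfn2AA relative to Mfn2wt: 12 of 27 fell and 1 rose (13 and 2 adjusted over the list alone), with a median of -0.37, and the list held with an estimated correlation (adjusted p = 0.0202). The hormone gene Fgf21 stood at -2.94 ± 0.40, the asparagine synthetase Asns at -2.64 ± 0.30, the mitochondrial folate enzyme Mthfd2 at -2.39 ± 0.26 and the cytokine gene Gdf15 at -1.91 ± 0.46. These genes were high in Mfn2wt hearts of this age, as the comparison with nontransgenic hearts below shows.

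Cell cycle genes fell in 15 of 38 members and rose in 0 (21 lower adjusted over the list alone). The median was -0.58 and adjusted p = 0.539 with an estimated correlation. Among them were the replication helicase genes Mcm6, at -1.45 ± 0.27, and Mcm5, at -1.24 ± 0.18, and outside the list the DNA glycosylase Neil3 stood at -2.13 ± 0.37. Mitochondrially encoded genes fell in 10 of 13 members (12 over the list alone, median -0.85, adjusted p = 0.539 with an estimated correlation). These included mt-Atp8 at -1.13 ± 0.25. Their share of all counts was 3.97% ± 0.375 (SD, n = 6) in Mfn2AA and 5.91% ± 1.10 (SD, n = 6) in Mfn2wt hearts. Fatty acid uptake and oxidation genes fell in 7 of 31 members (8 over the list alone, median -0.18, adjusted p = 0.679 with an estimated correlation). Among them was the thioesterase Acot2 at -1.06 ± 0.19. Mitochondrial ribosome genes fell in 9 of 76 (9 over the list alone, median -0.12, adjusted p = 0.679 with an estimated correlation).

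Higher in P21 Mfn2AA than Mfn2wt hearts were Olfr541, by 5.26 ± 0.52, Olfr45, by 5.05 ± 0.55, Endod1, by 3.12 ± 0.17, the growth inhibitor myostatin, Mstn, by 3.20 ± 0.51, the cytochrome P450 Cyp2e1, by 3.01 ± 0.56, Fgf1, by 2.26 ± 0.41, the matrix protein Spp1, by 2.14 ± 0.57, Clu, by 1.48 ± 0.22, and the protease inhibitor Timp1, by 1.45 ± 0.32. Tchhl1 stood at -3.59 ± 0.50, Macrod2 at -2.82 ± 0.16 and the anchoring protein Akap5 at -1.90 ± 0.18. Ion channel and gap junction genes rose in 4 and fell in 2 of 22 members (5 and 3 over the list alone, median 0.24, adjusted p = 0.679 with an estimated correlation).

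Markers of other cells moved in the same P21 comparison. Macrophage markers rose in 7 of 16 members (11 over the list alone, median 0.44, adjusted p = 0.539 with an estimated correlation). Adipocyte markers rose in 5 of 9, with the adipokine gene Adipoq at 4.08 ± 1.11, although the list as a whole did not pass (adjusted p = 0.0758). Atrial markers rose in 2 of 13 (7 over the list alone, median 1.85, adjusted p = 0.679 with an estimated correlation). With atrial and adipocyte marker scores as terms in the fit, chosen after the data were seen, 1813 genes were called and the stress response list had adjusted p = 0.0525 with an estimated correlation. Only 30 genes passed when the difference between the control lines was subtracted, and limma on FPKM called 1284 higher and 412 lower.

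Against tet-off hearts at P21, which ask what the mutant transgene adds to its driver, Mfn2AA differed in 78 of 13585 genes, 42 higher and 36 lower (n = 6 and 5). The lysozyme Lyz2 rose by 1.23 ± 0.21 and the macrophage gene Mpeg1 by 1.15 ± 0.20. In the macrophage list 2 of 16 members rose (10 adjusted over the list alone, median 0.37, adjusted p = 0.454 with an estimated correlation). Olfr541 rose by 6.08 ± 0.61, Scgb1c1 by 1.30 ± 0.18 and Mthfd2 by 1.47 ± 0.32, the single call among 27 stress response genes (2 over the list alone, median 0.12, adjusted p = 0.557 with an estimated correlation). The lipase Pnpla3 was lower, at -1.02 ± 0.19, and the imprinted growth regulator Grb10 at -0.48 ± 0.07. Interferon-stimulated genes had a median of -0.56 with 0 of 23 called and 18 lower over the list alone, and endoplasmic reticulum chaperones -0.23 with 1 of 20 called and 10 lower over the list alone (adjusted p = 0.276 with an estimated correlation for both).

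The 78 became 43, 12 and 10 without P21_Mfn2AA_10534-4, P21_Mfn2AA_10534-5 and P21_Mfn2AA_10534-8, 395 without P21_tetoff_10534-3, and 12, 16 and 17 without P21_tetoff_10549-3, P21_tetoff_10549-4 and P21_tetoff_10549-5. DESeq2 called 237, the title number as a block gave 23 (1 higher and 22 lower), of which 1 was among the 78, GC correction gave 141, and the marker scores as terms gave 251. The blocked comparison rests on P21_tetoff_10534-3, the only tet-off library with the title number of the Mfn2AA ones. With these scores 3 lists held with an estimated correlation, fetal sarcomere isoforms at adjusted p = 0.0146, interferon-stimulated genes at 0.0375 and endoplasmic reticulum chaperones at 0.0482.

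Mfn2wt hearts at P21 differed from nontransgenic hearts in 82 of 13585 genes, 54 higher and 28 lower (n = 6 and 6). The integrated stress response rose, in that 11 of 27 genes rose and 0 fell (15 adjusted over the list alone), with a median of 0.53 and adjusted p = 2.27e-07 with an estimated correlation. Fgf21 rose by 3.87 ± 0.48, Mthfd2 by 3.80 ± 0.30, Asns by 2.98 ± 0.32 and Gdf15 by 2.95 ± 0.52. The serine synthesis enzyme Phgdh rose by 1.95 ± 0.24, the amino acid transporter Slc7a5 by 1.82 ± 0.14 and the transcription factor Atf5 by 1.55 ± 0.10. Mean Mthfd2 was 50.9 ± 19.2 CPM (SD) in Mfn2wt and 3.56 ± 1.21 in nontransgenic hearts.

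Outside that list Tchhl1 rose by 3.92 ± 0.55 and Macrod2 by 3.04 ± 0.17 in P21 Mfn2wt hearts. The retinol esterase Lrat was lower, at -1.66 ± 0.29, the noradrenaline-synthesising Dbh at -1.16 ± 0.16, the calcium channel Cacna1g at -0.99 ± 0.14 and the pacemaker channel Hcn4 at -0.96 ± 0.19. In the ion channel list 2 of 22 members fell (5 over the list alone, median -0.26, adjusted p = 0.0708 with an estimated correlation), and atrial markers moved with it, at a median of -0.81 with 0 of 13 called (adjusted p = 0.997 with an estimated correlation). The count was 52 and 45 without P21_Mfn2wt_10583-2 and P21_Mfn2wt_10583-5, 52, 52 and 50 without P21_ntg_10547-3, P21_ntg_10547-5 and P21_ntg_10547-7, and 145 without P21_ntg_10583-1. DESeq2 called 142 genes, the marker scores as terms gave 128 and the title number as a block 54.

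The tet-off and nontransgenic lines at P21 differed in 222 of 13585 genes, 157 higher and 65 lower in tet-off (n = 5 and 6). Endod1 rose by 3.20 ± 0.18. A group of genes on chromosome 17 rose, with the histocompatibility genes H2-Q10 at 3.70 ± 0.58 and H2-Q2 at 2.34 ± 0.40, the glyoxalase Glo1 at 1.47 ± 0.19, Dnahc8 at 1.80 ± 0.37 and the glucocorticoid-induced Fkbp5 at 2.04 ± 0.32. Other rises were Zbtb16, at 1.69 ± 0.22, the survival gene Bcl2l1, at 0.84 ± 0.13, the clock gene Per2, at 0.72 ± 0.12, and Tnni1, at 3.74 ± 0.78. The neuronal Atcay was lower, at -1.68 ± 0.27, and the thiolase Acaa2 of fatty acid oxidation at -0.65 ± 0.13. Mitochondrially encoded genes had a median of -0.56 with 1 of 13 called and 11 lower over the list alone (adjusted p = 0.891 with an estimated correlation), and their counts made up 4.18% ± 1.08 (SD, n = 5) of tet-off and 5.77% ± 1.45 (SD, n = 6) of nontransgenic libraries. Without P21_ntg_10547-3 and P21_ntg_10547-5 in turn the count was 144 and 118, and without P21_tetoff_10549-4 and P21_tetoff_10549-5 142 and 131; limma on FPKM called 219 higher and 30 lower, and a fit of both groups alone called 145.

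**Figure D2:**
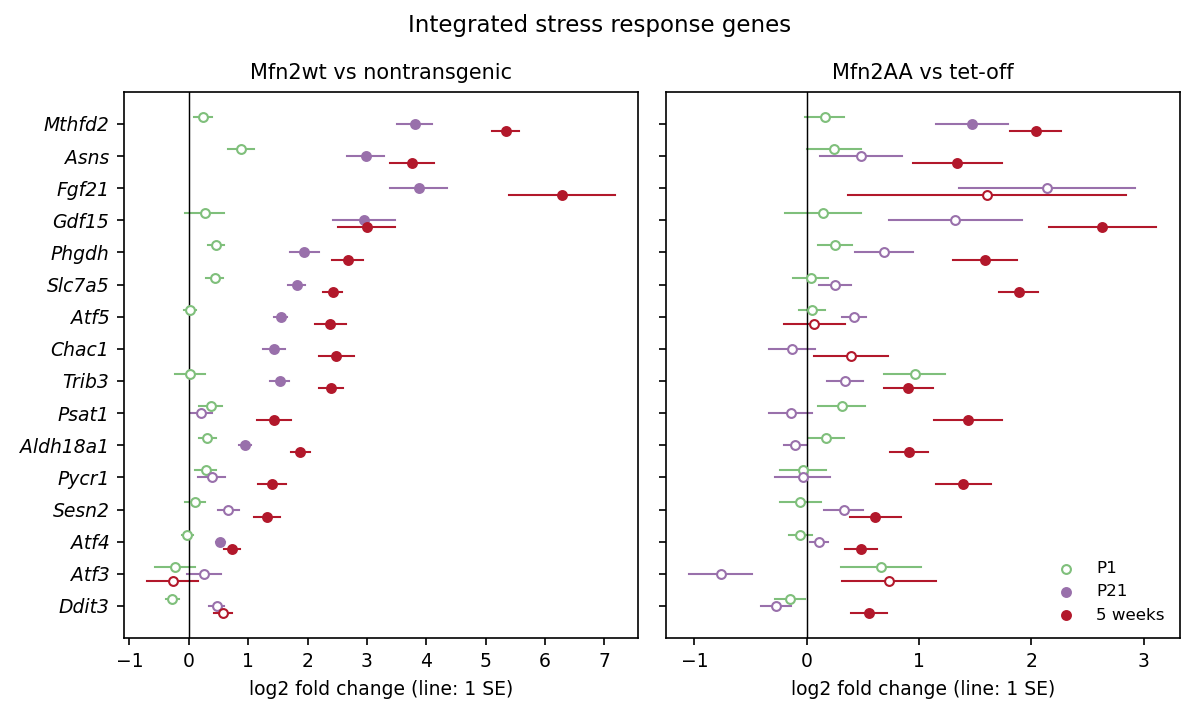
Log2 fold changes of integrated stress response genes in Mfn2wt over nontransgenic hearts (left) and Mfn2AA over tet-off hearts (right) at the 3 ages; points are estimates, filled where the gene passed the test, and lines are 1 SE. In Mfn2wt hearts Mthfd2 stood at 3.80 at P21 and 5.34 at 5 weeks, and in Mfn2AA hearts at 1.47 at P21.

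At 5 weeks transcripts of energy metabolism genes were lower and those of matrix and cardiac stress genes higher in Mfn2AA than Mfn2wt hearts. Fibroblast and macrophage markers were higher too, as given below. In whole tissue a change in cell shares cannot be told apart from a change within cells. The hearts differed in 5257 of 13661 genes, 2774 higher and 2483 lower in Mfn2AA (n = 4 and 4), and 2317 by at least 2-fold. Fatty acid uptake and oxidation genes fell in 29 of 31 members and rose in 0 (30 lower adjusted over the list alone, median -1.42, adjusted p = 0.00596 with an estimated correlation). These included the thioesterase Acot2 at -3.16 ± 0.29, the thiolase Acaa2 at -2.10 ± 0.15 and the carnitine transferase Cpt2 at -1.86 ± 0.15. Extracellular matrix genes rose in 34 of 35 members (34 over the list alone, median 2.49, adjusted p = 0.00596 with an estimated correlation). Among them were periostin, Postn, at 4.50 ± 0.73, tenascin, Tnc, at 3.83 ± 0.53 and collagen Col1a1 at 3.00 ± 0.37, and outside the list Ltbp2 stood at 4.38 ± 0.49.

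Every other mitochondrial energy list fell as well, in the sense that 0 of their members rose. In complex I 32 of 36 members fell (32 over the list alone, median -0.94, adjusted p = 0.0301 with an estimated correlation). They included Ndufs6 at -1.62 ± 0.22. In complexes II to IV 22 of 25 fell (22 over the list alone, median -0.93, adjusted p = 0.0301 with an estimated correlation). These included the cytochrome oxidase subunit Cox6a2 at -1.68 ± 0.31. In ATP synthase 15 of 17 fell (15 lower and 1 higher over the list alone, median -0.88, adjusted p = 0.0373 with an estimated correlation). Among them was Atp5g1 at -1.29 ± 0.15. In the citric acid cycle 19 of 20 fell (19 over the list alone, median -0.89, adjusted p = 0.0493 with an estimated correlation), with Idh2 at -1.21 ± 0.18. Ketone and branched-chain amino acid oxidation genes fell in 15 of 20 (17 over the list alone, median -0.97, adjusted p = 0.0598 with an estimated correlation).

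Regulators of mitochondrial biogenesis fell in 14 of 20 members (16 over the list alone, median -0.80, adjusted p = 0.0301 with an estimated correlation), among them the nuclear receptors Ppara, at -1.24 ± 0.14, and Esrrg, at -1.18 ± 0.11, and the helicase of mitochondrial DNA, Peo1, at -1.43 ± 0.13. Mitochondrial ribosome genes fell in 51 of 76 (56 over the list alone, median -0.64, adjusted p = 0.0493 with an estimated correlation), chaperones and proteases in 13 of 17 (14 over the list alone, median -0.67, adjusted p = 0.0234 with an estimated correlation), and fusion, fission and transport genes in 13 of 22 (14 over the list alone, median -0.56, adjusted p = 0.0598 with an estimated correlation). The mitophagy and autophagy list did not pass (adjusted p = 0.0647), with 2 of 37 members higher and 13 lower (2 and 13 over the list alone). All 13 mitochondrially encoded genes fell (13 over the list alone, median -1.77, adjusted p = 0.231 with an estimated correlation). They included mt-Atp6 at -1.98 ± 0.60. Their share of counts was 3.33% ± 1.49 (SD, n = 4) in Mfn2AA and 9.02% ± 3.12 (SD, n = 4) in Mfn2wt libraries.

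Contractile and electrical genes fell in 5-week Mfn2AA hearts. Adult sarcomere and calcium handling genes fell in 17 of 23 members and rose in 1 (18 and 1 over the list alone, median -0.82, adjusted p = 0.00596 with an estimated correlation). These included the calcium pump Atp2a2 at -1.46 ± 0.18, its inhibitor Pln at -1.60 ± 0.16 and Hrc at -1.73 ± 0.16. Ion channel and gap junction genes fell in 14 of 22 and rose in 1 (14 and 1 over the list alone, median -0.84, adjusted p = 0.0301 with an estimated correlation). Among them was the potassium channel Kcnj3 at -2.35 ± 0.22, and outside the list the potassium channel subunit Kcnv2 stood at -3.58 ± 0.24. Atrial markers, which share members with the channel list, rose in 2 and fell in 5 of 13 (2 and 5 over the list alone, median -1.11), and did not pass as a list (adjusted p = 0.108). Natriuretic and cardiac stress genes rose in 13 of 20 (14 over the list alone, median 1.53, adjusted p = 0.0332 with an estimated correlation). They included the natriuretic peptides Nppa at 2.52 ± 0.41 and Nppb at 2.60 ± 0.31, Ctgf at 2.89 ± 0.33 and Timp1 at 3.30 ± 0.67.

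Cell cycle genes rose in 34 of 37 members (34 over the list alone, median 1.97, adjusted p = 0.162 with an estimated correlation). These included the proliferation marker Mki67 at 3.02 ± 0.63, the kinase Cdk1 at 2.82 ± 0.49 and the cyclin Ccnb1 at 2.84 ± 0.77. Imprinted and fetal growth genes rose in 6 of 15 (8 over the list alone, median 0.68, adjusted p = 0.18 with an estimated correlation). Macrophage markers rose beside the matrix and cell cycle genes, in 13 of 17 members (14 over the list alone, median 1.45, adjusted p = 0.226 with an estimated correlation), and fibroblast markers in 12 of 15 (12 higher and 1 lower over the list alone, median 1.19, adjusted p = 0.00596 with an estimated correlation). Immediate early genes rose in 12 of 16 (12 over the list alone, median 1.29, adjusted p = 0.202 with an estimated correlation). They included Egr2 at 4.28 ± 0.52. The largest single rises included Sprr1a, a stress-induced protein, at 6.31 ± 0.79, the matrix protein Cilp at 4.88 ± 0.47 and the deiodinase Dio2 at 4.30 ± 0.50, and the largest falls included the uncoupling proteins Ucp1, at -5.40 ± 1.85, and Ucp3, at -2.87 ± 0.40, and the gluconeogenic Fbp2, at -3.35 ± 0.23. Ucp1 lost its call in 8 of 15 alternatives and stood at 1.95 when the control-line difference was subtracted.

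Stress response genes again stood lower in Mfn2AA than in Mfn2wt hearts at 5 weeks, with 15 of 28 lower and 4 higher (16 and 5 over the list alone, median -0.50, adjusted p = 0.0598 with an estimated correlation). Fgf21 was at -4.24 ± 0.64, Mthfd2 at -2.58 ± 0.19 and the glutathione-degrading Chac1 at -2.78 ± 0.29, while the haem oxygenase Hmox1 rose by 2.68 ± 1.00. Without 5wk_Mfn2AA_10287-8 that gene stood at -0.35 (adjusted p = 0.621), and it missed the threshold without 5wk_Mfn2wt_15926-4, 5wk_Mfn2wt_15931-9 and 5wk_Mfn2wt_15934-5 (adjusted p = 0.103, 0.111 and 0.112). The antioxidant list had 5 of 25 members higher and 8 lower (6 and 8 over the list alone), with a median and a mean of 0.13 and a set test pointing down (adjusted p = 0.443). Endoplasmic reticulum chaperones rose in 11 of 20 and fell in 3 (12 and 3 over the list alone, median 0.55, adjusted p = 0.252 with an estimated correlation). Interferon-stimulated genes rose in 8 of 24 (5 over the list alone, median 0.64, adjusted p = 0.49 with an estimated correlation), and clock genes fell in 8 of 18 and rose in 2 (8 and 2 over the list alone, median -0.31, but 0.03 on the FPKM scale, adjusted p = 0.0622 with an estimated correlation).

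**Figure D3:**
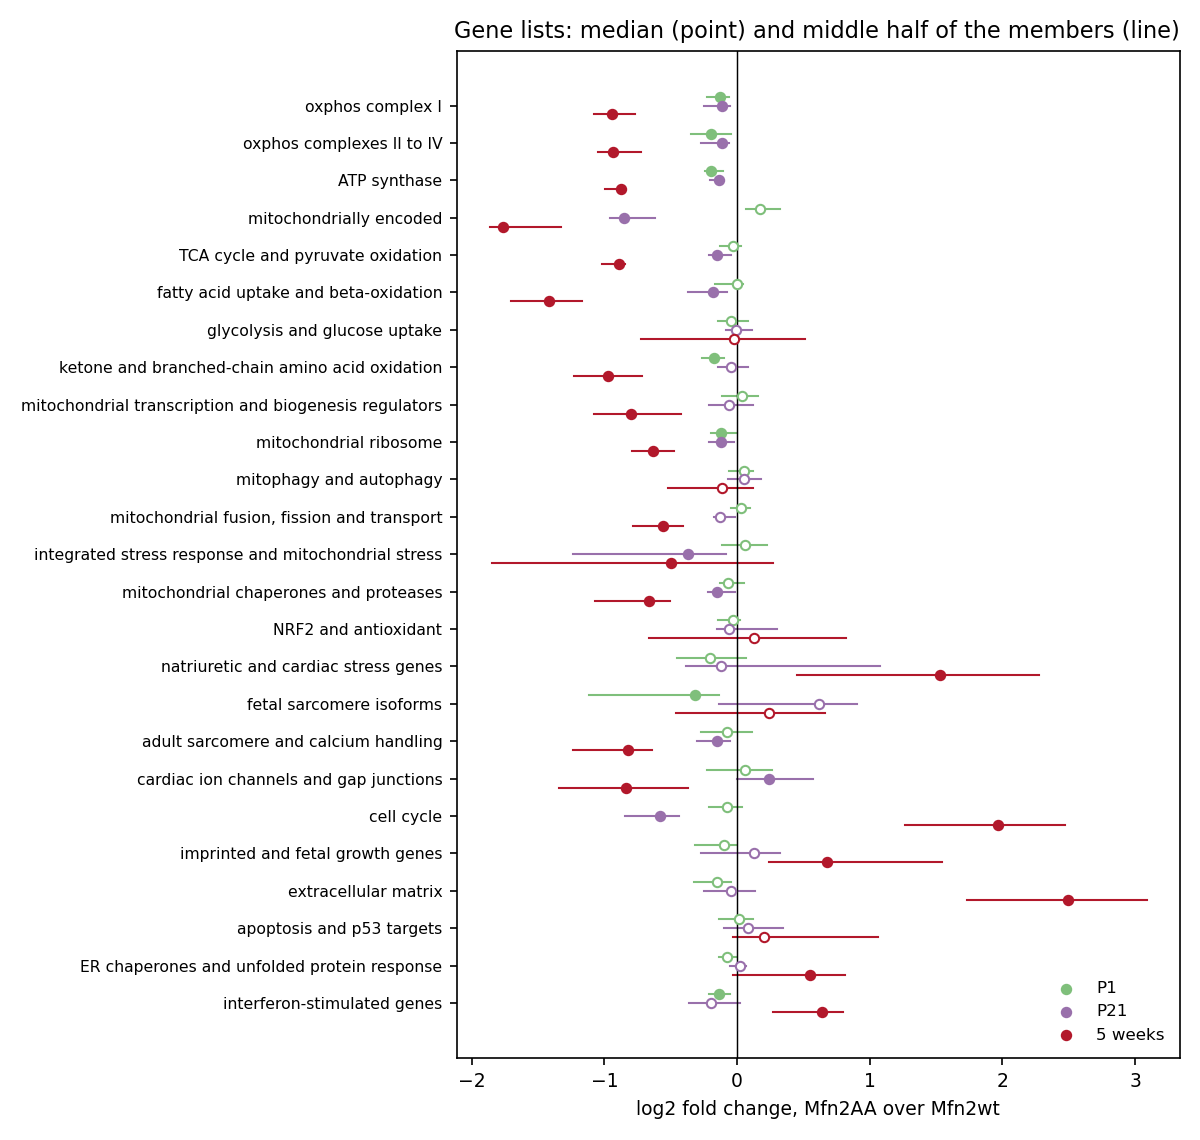
Log2 fold changes of the 25 pathway lists in Mfn2AA over Mfn2wt hearts at the 3 ages; points are medians of the members, filled where the set test with its preset correlation passed, and lines span the interquartile range of the members. At 5 weeks fatty acid oxidation lay at -1.42 and extracellular matrix at 2.49; 13 of the 24 lists called at 5 weeks held with an estimated correlation, 1 of 17 at P21 and 0 of 11 at P1, cell type and technical lists included.

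The Mfn2wt group of this age held 3 libraries of low depth (5wk_Mfn2wt_15926-4, 5wk_Mfn2wt_15931-9 and 5wk_Mfn2wt_15934-5, with total counts of 7396727, 7590577 and 10217586), against 16663207 to 23732780 in the Mfn2AA group. Without the 5 such libraries of this age, an alternative added after the data were seen, 2059 genes were called, 1944 of them among the 5257 and in the same direction, with the lone remaining Mfn2wt library assumed to vary like the other groups. Of the lists only fatty acid oxidation then held with an estimated correlation (adjusted p = 0.0234). On the FPKM scale the median of all genes stood at 0.33 (log2; 0.029 with edgeR), and limma called 4749 genes higher and 828 lower, and 2388 genes passed when the difference between the control lines was subtracted.

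**Figure D4:**
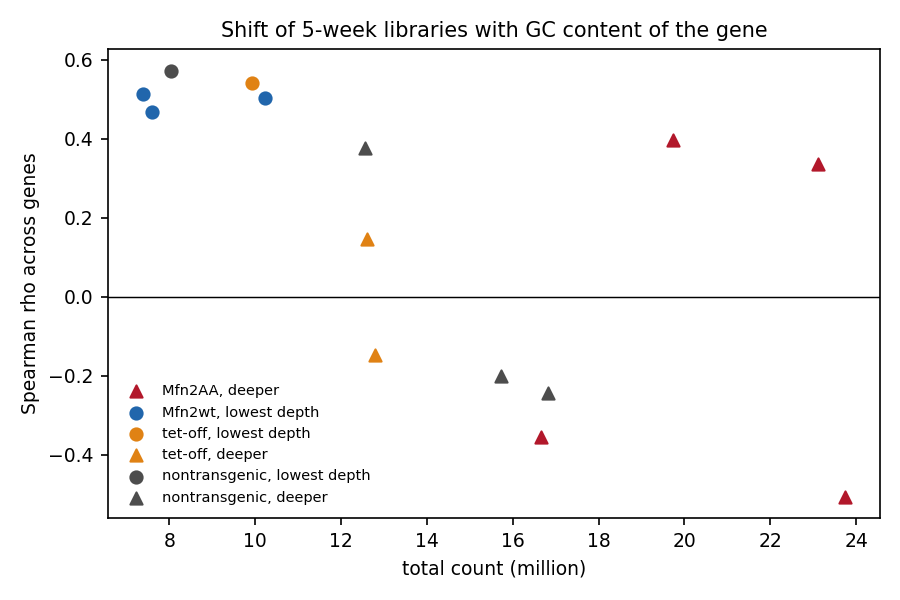
Spearman rho across genes between GC content and the log2 ratio of a 5-week library to its group, plotted against its total count; each point is a library. The 5 libraries of lowest depth lay at 0.47 to 0.57, 3 of them (Mfn2wt) against the same single library, and the deeper ones at -0.51 to 0.40.

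Against tet-off hearts, 5-week Mfn2AA hearts differed in 4781 of 13661 genes, 2584 higher and 2197 lower (n = 4 and 3). Extracellular matrix genes rose in 34 of 35 members (34 adjusted over the list alone, median 2.66, adjusted p = 0.00571 with an estimated correlation). These included the crosslinking oxidase Lox at 4.18 ± 0.63, Postn at 4.14 ± 0.81 and Timp1 at 4.16 ± 0.79, and outside the list collagen Col11a1 stood at 5.09 ± 0.85. Fatty acid oxidation genes fell in 29 of 31 (30 over the list alone, median -1.35, adjusted p = 0.00571 with an estimated correlation) and complex I genes in 30 of 36 (32 over the list alone, median -1.0, adjusted p = 0.0265 with an estimated correlation). Natriuretic and cardiac stress genes rose in 13 of 20 (14 over the list alone, median 2.07, adjusted p = 0.0249 with an estimated correlation). Among them was Nppa at 4.61 ± 0.51, or 8051 ± 2478 against 331 ± 192 CPM (SD). Cell cycle genes rose in 33 of 37 (34 over the list alone, median 1.74, adjusted p = 0.228 with an estimated correlation).

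In this comparison with the driver line the stress response rose, in 16 of 28 members with 3 lower (17 and 3 over the list alone, median 0.90, adjusted p = 0.0602 with an estimated correlation). The mitochondrial folate enzyme Mthfd1l stood at 2.89 ± 0.32, Gdf15 at 2.63 ± 0.48 and Nupr1 at 2.55 ± 0.36. The protease Adam8 rose by 5.17 ± 1.34. Chloride channel Clcn1 stood at -4.27 ± 0.37, Kcnv2 at -3.37 ± 0.25, the ephrin Efnb3 at -3.27 ± 0.21 and Hcn4 at -2.96 ± 0.36. Macrophage markers rose in 15 of 17 (16 over the list alone, median 1.73, adjusted p = 0.201 with an estimated correlation) and fibroblast markers in 12 of 15 (12 over the list alone, median 1.64, adjusted p = 0.00571 with an estimated correlation). On the FPKM scale the median of all genes stood at 0.20 (log2; 0.015 with edgeR), and limma called 3279 higher and 1016 lower. Without the 5-week libraries of lowest depth 4279 genes were called, 3783 of them among the 4781. With an estimated correlation 3 lists then held, fatty acid oxidation, extracellular matrix and fibroblast markers (each adjusted p = 0.0223), while complex I and the natriuretic genes did not (adjusted p = 0.120 for both).

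Mfn2wt hearts at 5 weeks differed from nontransgenic hearts in 53 of 13661 genes, 48 higher and 5 lower (n = 4 and 4). The integrated stress response rose again, in 15 of 28 members with 0 lower (18 adjusted over the list alone, median 1.36, adjusted p = 8.19e-07 with an estimated correlation). Fgf21 rose by 6.29 ± 0.89, Mthfd2 by 5.34 ± 0.23, Asns by 3.76 ± 0.37, Gdf15 by 3.00 ± 0.48, Phgdh by 2.68 ± 0.26 and Chac1 by 2.49 ± 0.29. Nppa rose by 2.52 ± 0.41, and atrial markers rose in 3 of 13 (5 over the list alone, median 1.24, adjusted p = 0.0837 with an estimated correlation). Mlana rose by 4.19 ± 0.66 and the repair gene Brca2 by 2.49 ± 0.31. Of 16 alternatives 2 each ended the calls of Nppa and Gdf15, and 1 each those of Fgf21, Chac1 and Mlana.

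The 5-week libraries of lowest depth were 3 Mfn2wt and 1 nontransgenic (5wk_ntg_15935-10) in this comparison. Without them only 5wk_Mfn2wt_15930-8 is left in the Mfn2wt group, so that fit cannot test whether the calls hold. The 53 became 32 and 35 without 5wk_Mfn2wt_15926-4 and 5wk_Mfn2wt_15934-5, and 31, 30 and 30 without 5wk_ntg_10287-6, 5wk_ntg_15927-6 and 5wk_ntg_15928-7; DESeq2 called 82 higher and 36 lower, limma on FPKM 27 and 7, and GC correction gave 59 and 15.

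The tet-off and nontransgenic lines at 5 weeks differed in 16 of 13661 genes, 8 higher and 8 lower in tet-off (n = 3 and 4), and the clock stood out. Of 18 clock genes 1 rose and 6 fell (3 and 9 adjusted over the list alone, median -0.51, adjusted p = 5.34e-04 with an estimated correlation). Arntl, an activator of the clock, rose by 2.49 ± 0.27, while Per2 was at -2.17 ± 0.36, Per3 at -1.39 ± 0.14, Dbp at -1.38 ± 0.22, Tef at -1.23 ± 0.13 and Hlf at -0.95 ± 0.13. The call was lost in 8 of 14 alternatives for Dbp, 6 for Per2 and 5 for Hlf. All tet-off libraries of this age share a title number that no nontransgenic one carries. Time of collection was not a term in the fit, so that it cannot be told apart from the line. Per2 had been higher in tet-off hearts at P21. Endod1 rose by 3.12 ± 0.27 and Smim3 by 2.39 ± 0.23. The count was 25, 7 and 6 without 5wk_ntg_10287-6, 5wk_ntg_15927-6 and 5wk_ntg_15928-7, 5, 10 and 5 without 5wk_tetoff_10289-1, 5wk_tetoff_10289-2 and 5wk_tetoff_10289-3, and 5 (4 of them among the 16) without the libraries of lowest depth. By unadjusted p edgeR gave 604 genes, DESeq2 called 24 higher and 40 lower, and a fit of both groups alone called 5.

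Postnatal maturation was read from nontransgenic hearts prepared together. The tissue labels give the whole heart at P1 and the left ventricle at the later ages, while the protocol names ventricular apexes, so that tissue is confounded with age from P1 to P21, in the maturation sets too. Atrial markers did not pass as a list from P1 to P21 (adjusted p = 0.553), with 5 of 13 higher and 1 lower (5 and 0 over the list alone). From P1 to P21 (n = 6 and 3) 7794 of 13534 genes changed, 3931 higher and 3863 lower, and 2553 by at least 2-fold. All 40 cell cycle genes fell (40 adjusted over the list alone, median -2.42, adjusted p = 0.166 with an estimated correlation). These included Ccnb1 at -3.27 ± 0.33. Imprinted and fetal growth genes fell in 16 of 18 (17 over the list alone, median -2.22, adjusted p = 4.13e-04 with an estimated correlation). Among them were Dlk1 at -5.54 ± 0.25, Igf2bp1 at -5.17 ± 0.27 and H19 at -4.35 ± 0.24. The fetal troponin Tnni1 was lower, at -6.03 ± 0.55.

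Complex I genes rose from P1 to P21 in 33 of 36 members (33 over the list alone, median 0.69, adjusted p = 0.5 with an estimated correlation), citric acid cycle genes in 19 of 20 with 1 lower (19 and 1 over the list alone, median 0.66, adjusted p = 0.339 with an estimated correlation) and ketone and branched-chain amino acid genes in 18 of 20 with 1 lower (18 and 1 over the list alone, median 0.98, adjusted p = 0.166 with an estimated correlation). The mitochondrial creatine kinase Ckmt2 rose by 3.34 ± 0.12, Cox7a1 by 2.35 ± 0.19, the pyruvate carrier Mpc1 by 2.11 ± 0.17 and the ketone enzyme Oxct1 by 2.47 ± 0.10. Adult sarcomere and calcium genes rose in 16 of 23 with 2 lower (16 and 2 over the list alone, median 0.83, adjusted p = 0.229 with an estimated correlation), and outside the list Kcnv2 rose by 6.56 ± 0.40. Macrophage markers rose beside them in 14 of 15 with 1 lower (14 and 1 over the list alone, median 2.1, adjusted p = 0.178 with an estimated correlation). On the FPKM scale the median of all genes stood at -0.18 (log2; -0.016 with edgeR), and limma called 2526 higher and 5584 lower.

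From P21 to 5 weeks (n = 3 and 4) 3035 of 13534 genes changed, 1573 higher and 1462 lower. Cell cycle genes fell further, in 35 of 40 (37 lower and 1 higher adjusted over the list alone, median -1.38, adjusted p = 0.167 with an estimated correlation). Ketone and branched-chain amino acid genes rose in 13 of 20 (15 over the list alone, median 0.50, adjusted p = 0.0718 with an estimated correlation). They included the ketone dehydrogenase Bdh1 at 5.65 ± 0.26. Extracellular matrix genes fell in 19 of 35 and rose in 1 (22 and 3 over the list alone, median -0.62, adjusted p = 0.405 with an estimated correlation), the imprinted H19 stood at -1.70 ± 0.21 and Igf2 at -1.38 ± 0.13. Adipocyte markers rose in 5 of 10 (6 over the list alone, median 2.57, adjusted p = 0.457 with an estimated correlation). These included Cidec at 5.83 ± 1.16. Erythroid markers fell in 3 of 5 (3 over the list alone, median -1.95, adjusted p = 0.0634 with an estimated correlation). Without P21_ntg_10547-1 in its library of this batch the count was 1426.

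The difference between Mfn2AA and Mfn2wt hearts itself changed with age. From P1 to P21 it changed in 45 of 14610 genes, 18 up and 27 down, and the stress response list held with an estimated correlation (0 of 28 members up and 7 down, 11 down adjusted over the list alone, median -0.45, adjusted p = 2.27e-04). Among them were Chac1 at -2.80 ± 0.62, Mthfd2 at -2.52 ± 0.36, Asns at -2.44 ± 0.45 and the kinase-like Trib3 at -1.78 ± 0.29. The 45 became 28, 20 and 21 without P1_Mfn2AA_10586-3, P1_Mfn2AA_10586-7 and P1_Mfn2AA_10619-1, 25 without P1_Mfn2wt_10546-3, and 29 and 28 without P21_Mfn2AA_10534-5 and P21_Mfn2AA_10534-8, and DESeq2 called 45 up and 43 down.

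From P21 to 5 weeks the difference changed in 5261 of 14610 genes, 2594 up and 2667 down. With an estimated correlation 6 lists held, all at adjusted p = 0.0435. Cell cycle moved up in 37 of 40 members (38 adjusted over the list alone, median 2.69), extracellular matrix in 33 of 35 (33, median 2.35) and natriuretic and cardiac stress genes in 12 of 20 with 1 down (12 and 1, median 1.71). Fatty acid oxidation moved down in 28 of 31 (29 down and 1 up, median -1.22), biogenesis regulators in 13 of 21 (15 down and 1 up, median -0.74) and ion channels in 16 of 22 with 1 up (16 and 1, median -1.17). Atrial markers moved down beside the channels in 5 of 13 (6 over the list alone, median -1.95, adjusted p = 0.573 with an estimated correlation). Their mean log2 CPM ran from 3.35 to 7.33 among the P21 Mfn2AA libraries. Marker scores were not tried as terms for this contrast, so atrial tissue cannot be told apart from genotype in it. Cilp stood at 5.21 ± 0.50, Postn at 4.97 ± 0.56, Gdf15 at 2.88 ± 0.58, Pink1 at -1.68 ± 0.20, Mfn2 at -0.88 ± 0.16 and Bmp10 at -9.01 ± 1.71. Without the 5-week libraries of lowest depth this contrast rests on the lone Mfn2wt library 5wk_Mfn2wt_15930-8 at that age, so that fit cannot test whether the calls hold.

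Genes that mature after birth were then followed in Mfn2AA against Mfn2wt hearts, with sets taken from libraries outside each contrast. At P1 the 1217 genes at least 2-fold higher at P21 than at P1 had a median of 0.022 (adjusted p = 0.371 over the 6 sets) and the 1147 lower ones -0.0040 (adjusted p = 0.736). At P21 the higher-with-age set of 1398 genes stood at 0.15, with 279 called higher and 70 lower (adjusted p = 7.6e-07, and adjusted p = 0.00652 with an estimated correlation). The lower-with-age set of 946 stood at -0.10, with 51 higher and 127 lower (adjusted p = 0.0192, and adjusted p = 0.489 with an estimated correlation). At 5 weeks the medians had the other sign, though the change of the sets with age was not tested. The 949 lower-with-age genes stood at 0.73, with 446 higher and 74 lower (adjusted p = 2.9e-09, and adjusted p = 0.0445 with an estimated correlation). The 1395 higher-with-age genes stood at -0.13, with 341 higher and 472 lower (adjusted p = 0.00767, and adjusted p = 0.0114 with an estimated correlation). At 5 weeks smaller medians of the same sign appeared without the mutant line. The higher-with-age set stood at -0.069 in tet-off and -0.053 in Mfn2wt against nontransgenic hearts (unadjusted p = 0.00612 and 0.005 with an estimated correlation). The lower-with-age set stood at 0.087 and 0.083 (0.227 and 0.18). At P21 the higher-with-age set stood at -0.058 in Mfn2wt against nontransgenic hearts (0.0249), some of which also defined the sets. In Mfn2AA against tet-off it stood at 0.073.

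The responses of the transgenic lines to their own controls, Mfn2AA against tet-off and Mfn2wt against nontransgenic, share no library. At 5 weeks 19 genes rose in both, where independent lists would share 9.08. Of these 5 kept both calls under every setting tried, the amino acid and folate genes Mthfd2, Phgdh, Aldh18a1 and Slc7a5 and the stress gene Trib3, while 14 lost 1 of them or both in some. Smim5 and Colq fell in both (0.804 expected), but of 16 alternatives 9 ended the call of Smim5 in Mfn2wt hearts and 12 in Mfn2AA hearts, and 6 that of Colq in Mfn2wt hearts. Another 4 genes moved in opposite directions, among them Macrod2. Across genes, which are not independent replicates, Pearson's r was 0.22 and Spearman's rho 0.20. At P21 Mthfd2 rose and Pnpla3 fell in both lines, but neither call in Mfn2AA against tet-off was firm. That of Mthfd2 was lost in 10 of 20 alternatives (adjusted p up to 0.643), among them without P21_Mfn2AA_10534-1, P21_Mfn2AA_10534-4, P21_Mfn2AA_10534-5 and P21_Mfn2AA_10534-8 (0.0604, 0.0691, 0.0757 and 0.0753) and without P21_tetoff_10549-3, P21_tetoff_10549-4 and P21_tetoff_10549-5 (0.1001, 0.0995 and 0.0990). That of Pnpla3 was lost in 3 of 20, without P21_Mfn2AA_10534-8 and P21_tetoff_10549-3 (0.0524 and 0.0644) and with the title number as a block (0.117). That block, which also gave the 0.643 of Mthfd2, rests on P21_tetoff_10534-3 as control. At P1 no called gene was shared, with edgeR calls of 1 and 20 and unadjusted counts of 1140 and 1755.

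Libraries made again from the same RNA show how far a batch moves values. For 3 P21 hearts, with the heart as a block, 1835 of 12994 genes differed between the P1 batch and the P21 batch, 51 by at least 2-fold, and 2 without the block. For 3 hearts of 5 weeks 1275 of 12491 genes differed from the 5-week batch, 385 by at least 2-fold, and 327 without the block. Mitochondrially encoded genes rose in 6 of 13 in the first (8 adjusted over the list alone, median 0.53) and fell in 9 of 13 in the second (10 lower and 1 higher over the list alone, median -1.42), with adjusted p = 0.833 and 0.832 with an estimated correlation. Leaving out hearts gave 93, 562 and 4084 genes without P21 hearts P21_ntg_10547-1, P21_ntg_10547-2 and P21_ntg_10547-5, and 2388 and 3199 without 5-week hearts 5wk_ntg_15927-6 and 5wk_ntg_15935-10; DESeq2 called 445 for the P21 hearts and the absence of a filter gave 2892 for the 5-week hearts.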

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

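Each result here met a rule set in advance, and no test in this part was chosen only after its result was seen. Among 55 tests of single libraries against their group 9 found a library apart, where chance gives about 1 in 20.

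Human transgene signal stood apart in 5 libraries labelled as without the transgene, and its source was not tested. It was 97.6 FPKM in the nontransgenic P1 library P1_ntg_10582-5, where the next library of the group had 29.1. It was 155 FPKM in the tet-off P1 library P1_tetoff_10587-1 (next 39.8) and 362 FPKM in the tet-off P21 library P21_tetoff_10534-3 (next 26.0). Without that P21 library the 78 calls of Mfn2AA against tet-off became 395. It is also the only tet-off library of that age with the title number of the Mfn2AA ones, so its removal makes title number and genotype the same split. At 5 weeks it was 20.02 FPKM in 5wk_ntg_15928-7 (next 5.85) and 177 FPKM in 5wk_ntg_15933-3 of the P1 batch (next 16.5). These libraries lay far from the others of their group, and their values stayed below those of every transgenic library of their age. Groups of 3 libraries were too small for this test. In 1 of them, 5-week tet-off, 5wk_tetoff_10289-1 had 190 FPKM where the others had 3.96 and 23.7. It is a control of the 5-week Mfn2AA hearts, whose lowest library had 336.

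Mouse Mfn2 was lowest in the P21 Mfn2AA library P21_Mfn2AA_10534-5, at 234 FPKM where the next had 267, and in the P21 Mfn2wt library P21_Mfn2wt_10547-9, at 204 FPKM where the next had 239. Rn45s took 14.1% of counts in the nontransgenic P1 library P1_ntg_10582-1, and 5.76% in the next. Mitochondrially encoded genes took 4.67% in the P21 Mfn2AA library P21_Mfn2AA_10534-8, and 4.01% in the next.

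The effect of Mfn2AA against Mfn2wt differed between ages by a test of the difference itself, in 45 genes between P1 and P21 and in 5261 genes between P21 and 5 weeks. Age and batch are confounded in both tests, and the order of the lines in transgene level turned between P21 and 5 weeks.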

How the results depend on the processing

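The fits without the 5-week libraries of lowest depth, with marker scores and with GC correction were chosen after the data were seen. Of the results under settings chosen in advance, other than leaving out a library, 87 stayed within 1.5 times the count or kept their side of the threshold, 40 moved, 3 grew stronger and 1 weaker, and of the added ones 14 stayed and 7 moved. The balance of higher and lower calls turned in some fits, as in Mfn2wt against nontransgenic at P1 (12 and 8, 13 and 17 with GC correction), the control lines at P1 (108 and 69, 106 and 110 with GC correction), Mfn2AA against tet-off at P21 (42 and 36, 1 and 22 with the title block, 123 and 128 with marker scores), Mfn2wt at P21 (54 and 28, 308 and 513 against tet-off), Mfn2AA against Mfn2wt at P21 (1021 and 841, 7 and 23 after subtraction of the control lines) and at 5 weeks (2774 and 2483, 959 and 1100 without the lowest depth). Of the named genes in Mfn2AA against Mfn2wt, Endod1 at P21 went to -0.077 and Ucp1 at 5 weeks to 1.95 when the difference between the control lines was subtracted. Hmox1 at 5 weeks ranged from -0.35 without 5wk_Mfn2AA_10287-8 to 3.54 without 5wk_Mfn2wt_15930-8. Over the 180 named genes in their comparisons, 111 kept their call under every setting tried, and 237 of 3084 values fell short of the threshold, and 3 more did so with the sign turned. Some genes were left out of the text because many settings ended their call, so these shares hold for the named genes alone and are no rate for all called genes. Ucp1 fell short without 5wk_Mfn2AA_10287-8, 5wk_Mfn2AA_10289-7, 5wk_Mfn2AA_10289-8, 5wk_Mfn2AA_10289-9 and 5wk_Mfn2wt_15934-5 (adjusted p = 0.0572, 0.0686, 0.0640, 0.0651 and 0.143). The cause of each change below was not tested, except where fewer libraries were fitted.

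With DESeq2 the P1 counts were 62 (Mfn2AA against Mfn2wt), 16 (against tet-off), 183 (Mfn2wt against nontransgenic) and 432 (control lines). At P21 they were 237 (Mfn2AA against tet-off) and 142 (Mfn2wt against nontransgenic), at 5 weeks 118 (Mfn2wt against nontransgenic) and 64 (control lines), 88 for the change of the line difference from P1 to P21, and 445 for the same RNA at P21. On FPKM with limma they were 6, 7, 12 and 93 at P1, in the same order, 51 (Mfn2AA against tet-off, P21) and 34 (Mfn2wt against nontransgenic, 5 weeks). Without a filter Mfn2wt against nontransgenic gave 42 at P1, and the same RNA at 5 weeks 2892.

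Fits of 2 groups alone, with fewer samples, gave 7, 2 and 8 at P1 (Mfn2AA against Mfn2wt and tet-off, Mfn2wt against nontransgenic), 19 and 145 at P21 (Mfn2AA against tet-off, control lines) and 5 for the control lines at 5 weeks. Subtracting the difference between the control lines gave 1, 30 and 2388 genes in Mfn2AA against Mfn2wt at P1, P21 and 5 weeks. With nontransgenic hearts as control Mfn2AA gave 191 at P1 and 914 at P21. With tet-off hearts as control Mfn2wt gave 80, 821 and 130 at the 3 ages. The title number as a block gave 1 for Mfn2wt against nontransgenic at P1, and 23 (Mfn2AA against tet-off) and 54 (Mfn2wt against nontransgenic) at P21. Without the heart as a block the same RNA gave 2 genes at P21 and 327 at 5 weeks.

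GC correction gave 141 for Mfn2AA against tet-off at P21, where marker scores as terms gave 251, and 128 for Mfn2wt against nontransgenic. Without the libraries of lowest depth the 5-week counts were 2059 (Mfn2AA against Mfn2wt), 9 (Mfn2wt against nontransgenic) and 5 (control lines), and 3454 for the change of the line difference.

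The estimated correlation left 35 list calls over the 18 comparisons. In the maturation sets at P1 the higher-with-age median was 0.12 against tet-off and 0.10 for changes of at least 4-fold, both past the threshold, and the lower-with-age median was -0.082 with sets from P21 to 5 weeks. With an estimated correlation the set against tet-off kept its side of the threshold, while the set of 4-fold changes and the set from P21 to 5 weeks missed it. At P21 the lower-with-age set, at -0.10, missed the threshold with an estimated correlation. At a mean of at least 10 CPM 11 genes rose and 1 fell in both transgenic lines at 5 weeks.

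Leaving out each library in turn gave these ranges. At P1 they were 3 to 14 (Mfn2AA against Mfn2wt), 1 to 22 (against tet-off), 1 to 115 (Mfn2wt against nontransgenic) and 73 to 355 (control lines). At P21 they were 10 to 395 (Mfn2AA against tet-off), 45 to 145 (Mfn2wt against nontransgenic) and 118 to 214 (control lines). At 5 weeks they were 30 to 57 (Mfn2wt against nontransgenic) and 5 to 25 (control lines). They were 1426 to 2867 from P21 to 5 weeks, 20 to 58 for the change of the line difference from P1 to P21, and 93 to 4084 (P21) and 1156 to 3199 (5 weeks) for the same RNA. In simulated data with the depths and group sizes of the genotype comparisons 7.46% to 69.7% of 1.5-fold changes were called, and depth apart from group size was not tested.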

Other observations

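The tests of genome position, of the re-made library, of the control lines and of the marker scores in this part were chosen only after the results were seen. Some called genes lay side by side on the genome. Endod1 (chromosome 9, 14353990 to 14381242) was higher in tet-off than nontransgenic hearts at every age, and higher in Mfn2AA than Mfn2wt hearts at P1 and P21. Macrod2 (chromosome 2, 140395430 to 142390050) was higher in Mfn2wt than nontransgenic hearts at every age, and Sel1l2 beside it, tested at P21 alone, rose there by 4.54 ± 0.72. Ndufaf5 (140170646 to 140205252), also near it, was lower with it in Mfn2AA than Mfn2wt hearts at P1, where 25 of 1000 draws gave such a pair. The olfactory receptor genes Olfr45 (chromosome 7, 140690907 to 140691842) and Olfr541 (140704253 to 140705191) were higher in Mfn2AA than tet-off hearts at P21, as was Scgb1c1 (140845565 to 140846769) near them. At P1 Olfr541 was called and Scgb1c1 was not (adjusted p = 0.623), and at 5 weeks neither was (adjusted p = 0.0801 and 0.308). Cyp2e1 (140763832 to 140774977), between those genes, was not called against tet-off at P21 (adjusted p = 0.348). It was called at 5 weeks, at 2.80 ± 0.91 (adjusted p = 0.0252). At that age 8 of the 18 tested neighbours of Olfr541 within 500 kb were called, where 35.0% of all tested genes were.

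Among genes higher in tet-off than nontransgenic hearts at P21, 40 pairs lay within 500 kb, against a 95th percentile of 19 in 1000 random draws. On chromosome 17 lay 19 of them, most in the histocompatibility region that holds H2-Q10 (35470089 to 35474563). Others lay around Glo1 (30592862 to 30612659), and Fkbp5 (28399095 to 28486112) formed a pair with Brpf3 alone. At P1 12 pairs lay within 500 kb (95th percentile 10), 1 of them on chromosome 17, and at 5 weeks 0 among 8 genes. Glo1 was called at P1 and P21 and not at 5 weeks. Genes lower in tet-off hearts gave 4 pairs at P21 (95th percentile 5) and 3 at P1 (5), and genes higher in Mfn2wt than nontransgenic hearts gave 2 at P21 (3). Genes higher in Mfn2AA hearts at P21 also lay close, with 748 pairs against Mfn2wt (95th percentile 577) and 7 against tet-off (2). Genes lower in them gave 268 pairs against Mfn2wt, under the median draw of 336, and 0 against tet-off (2). The draws took tested genes at random and do not allow for neighbours that change together. Reads shared between paralogs are argued against, as 36 pairs remained without genes of like names (95th percentile 18). Genome segments that differ between the lines, carried with a transgene or from another strain, may explain the 40 pairs, as a candidate found in these data, but a segment held by all animals of a line would show at each age and could move genes in both directions, and no biological explanation was tested.

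The 5-week libraries of lowest depth shared a shift against the deeper libraries of the same group and genotype, with a rho with GC content of 0.54 and 0.57 in 2 of them, while the 3 Mfn2wt ones (0.47 to 0.51) are all set against the same single library and so are not separate evidence. Deeper libraries lay at -0.51 to 0.40 against the rest of their group, 1 of 10 pairs of them differed with a rho of 0.60 in size, and their spread across genes (0.211 to 0.545) overlapped that of the libraries of lowest depth (0.345 to 0.521). GC content remains open and may be part of the cause, with a rho of 0.59 between the mean shift and GC content, and of 0.58 over the 2 libraries alone. Counting noise at low depth as the whole source of the spread is argued against for these 5 libraries. Their smallest spread, 0.345, was 4.13 times the largest given by thinning deeper libraries, 0.0837. As that spread also holds the spread between hearts, a part from counting noise stays open. Gene length (rho -0.10) cannot be told apart from other causes, because its rho lies between the bounds set for it. The same holds for the RNA of the hearts, a test that rests on 1 heart. The re-made library of that heart lay at -3.77% of the distance of its first library. No other biological explanation was tested.

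Of the 1862 genes called in Mfn2AA against Mfn2wt at P21, 86.9% differed between the control lines in the same direction, and 129 were called there in that direction and 1 in the other. The control-line difference had a median of 0.18 in the direction of the call, which is 36.2% of the median of 0.48 between the transgenic lines. It may account for part of the calls. In the direct comparison it cannot be told apart from the effect of the mutation, since line and mutation are the same split. Subtracting it, as given above, takes nontransgenic hearts as the control of Mfn2wt. The labels used here do not say whether Mfn2wt hearts carry the driver. Atrial and fat tissue in the samples as the whole source is argued against, as 1813 genes were called with the marker scores as terms, 1326 of them among the 1862. A part of the calls stays open, and with these terms 0 of 36 lists held with an estimated correlation.

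Other splits of the same libraries were fitted for each comparison. At P1 chance was not excluded for Mfn2AA against Mfn2wt (17 genes, highest other split 224, and 3 of 35 splits as many), Mfn2AA against tet-off (1, highest 8, 11 of 56) or Mfn2wt against nontransgenic (20, highest 83, 5 of 100), nor at P21 for Mfn2AA against tet-off (78, highest 660, 5 of 100). Some splits gave several times the real count, which may reflect a structure among the libraries other than genotype and was not tested.

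A chance draw of single libraries was argued against for the control lines at P1 (177, highest other 7, 1 of 100). At P21 it was argued against for Mfn2AA against Mfn2wt (1862, highest 47, 1 of 100) and Mfn2wt against nontransgenic (82, highest 2, 1 of 100). For the control lines at P21 (222, 2 of 100) it was argued against too, although another split gave 463. At 5 weeks a chance draw was argued against in each comparison, with 1 of 35 splits as many. These were Mfn2AA against Mfn2wt (5257, highest 1), Mfn2AA against tet-off (4781, highest 2799), Mfn2wt against nontransgenic (53, highest 0) and the control lines (16, highest 2). The same held from P1 to P21 (7794, highest 18, 1 of 84) and from P21 to 5 weeks (3035, highest 767, 1 of 35). It held for the changes of the line difference as well (45, highest 4, and 5261, highest 2030, 1 of 40 each). These shares were not adjusted over the comparisons. No title number was shared between Mfn2AA and Mfn2wt, or between tet-off and nontransgenic, libraries of an age. As the splits move single libraries, they cannot exclude a difference between title numbers. For the same RNA the 4 splits are too few, with 1835 and 1275 genes, 1 split as many and a highest other of 0 in each.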
